A study of Mus musculus with 2 samples.

How the data were processed

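Poly(A)-selected RNA of adult mouse heart was measured in 2 libraries of 1 group, with group and replicate number taken from the labels. The authors deposited, for each library, a table of genes and a table of transcripts on the mm10 build with the GENCODE M4 annotation, per the notes that accompany the tables. The aligner, the quantification program and their versions are not given in the sources used here. The deposited expected counts are estimated fragments per gene or transcript, not whole because fragments shared between transcripts are divided, per the file headers. The deposited TPM values, as maximum likelihood and posterior mean estimates, divide those counts by effective length and are scaled to the same sum in each library, per the file headers. The deposited FPKM values scale the counts by effective length and by library depth, per the file headers, and were used only as an alternative. The percent of a gene held by each transcript was deposited by the authors in the transcript tables, per the file headers, and shares were computed here again from TPM. The tables also hold other deposited columns, a posterior standard deviation of the count and the annotated and effective lengths, per the file headers.

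On the mm9 build the authors deposited a list of junctions and a list of contigs with no library named. In the junction list the deposited count of reads per junction is a whole number and equals the sum of the numbers marked R1 and R2 in the junction name. Which library R1 and R2 stand for is not stated, so they were given to no sample. The contig list holds a deposited signal, an expression level per contig. Both lists hold a deposited display score, which was not used, and a deposited significance fraction from 0 to 1 whose definition is not given in the sources used here. Coordinates of the builds were never mixed.

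The gene tables held 43346 gene identifiers, of which 42462 (98.0%) matched GENCODE M21 on the same assembly by identifier, the source of symbols, coordinates, biotypes and GC content. A further 26248 numbered entries held no counts. There were 96 spike-in sequences and 1 phiX sequence, without counts for the latter, and these stayed out of gene tests. Ahsp, Hbb-b1 and Hbb-b2 of the erythroid list matched no gene and were not analysed here. Values of some single genes are not reported here. Totals were 57464573 and 62912053 estimated counts. With TMM-scaled gene totals, 3 counts, the floor used for a gene at 0, stand for 0.0555 and 0.0464 CPM.

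Expected counts were rounded to whole numbers for count tests. TMM factors (0.957 and 1.04) and the common dispersion came from edgeR 4.0.16 in R 4.3.3, the dispersion with an intercept-only design over 15183 genes kept by edgeR's expression filter with at least 10 counts. Genes with at least 20 counts over both libraries were compared with a two-sided exact binomial test given TMM-scaled sizes, taken as 2 times the smaller tail, with Benjamini-Hochberg adjustment at 0.05 and a fold of at least 2. Each fixed list with at least 4 members of mean CPM 1 or more was placed by its median log2 ratio (CPM + 0.5) among 10000 random lists of the same size matched on mean expression in 20 bins. Lists too small for this, namely skeletal muscle, liver, thymus, cell cycle and RNAs without a poly(A) tail, were described by calls and levels. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

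The 33 gene lists (459 genes), the 30 pairs, the 24 genes for transcripts, the tests and the rule for named genes were fixed before the data were examined. The rule named up to 4 members of highest mean TPM per list, the 10 genes of highest mean TPM, all pair and transcript genes, all sex genes, and the 10 called genes of largest fold in each direction with a mean CPM of at least 10. Called members of the lists beyond these, the 3 X-linked genes, Lum, Gm28437, the set of 6 chromosome 1 pseudogenes, Gm42418, mt-Rnr1 and mt-Rnr2 were chosen after their values were seen. The same holds for Cry1, Arntl and Clock.

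The tests were tested on simulated data for the difference between the libraries. With counting noise alone (16127 genes), 47.5% of 99 genes changed 2-fold and 96% of 100 changed 4-fold were called, and 0.0189% of unchanged genes. With the dispersion of these libraries (16072 genes), which was estimated from the difference between them, 51.5% and 91% were called, and 8.94% of unchanged genes. A 2-fold change lies on the fold limit itself, so 47.5% and 51.5% do not measure the power of the test. Without the fold limit 86.9% of genes changed 2-fold were called with counting noise alone and 89.9% with the dispersion. Of unchanged genes 0.0629% and 63.8% were then called. A list of 20 genes shifted 1.5 times lay at percentile 100, and of 200 unshifted lists 5% lay outside. The unshifted lists were random draws of genes simulated independently, so that share was set by the method. The simulation held no trend with GC content and no related genes moving together, so 5% is not the error rate for the fixed lists. A simulated coefficient of variation of 0.275 was estimated as 0.279 (15593 genes).

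Alternatives covered scaling (DESeq2 1.42.0 size factors, total counts), filters, fold limits, pseudocounts, units, posterior mean TPM, matching of random lists and leaving out each library. Random lists matched also on GC content or transcript length used 10 bins of expression and 5 of that property. GC-corrected calls and dispersion, lists matched on GC content, calls without markers of other cells and tissues, the correlation without mitochondrial genes and TPM without mt-Atp8 were chosen after seeing the data. Further markers outside the fixed lists and the named genes (15 of lung, 9 of red blood cells and 10 of fat) were also chosen after seeing the data, for the tests of other tissue. The step of 0.01 used to say whether the correlation or the coefficient of variation moved was also set after values of the latter had been seen.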

Results

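The series profiled poly(A)-selected RNA from the heart of adult C57BL/6J mice, an inbred laboratory strain, at 8 weeks of age. The labels describe stranded paired reads of 76 nucleotides from RNA longer than 200 nucleotides. They name 1 group of 2 libraries, called biological replicates, with separate biosamples and 1 shared donor record. Sex-linked transcripts, described below, argue against 1 animal as the source of both libraries. Xist had 13725 counts in replicate 1 and 13 in replicate 2, and 4 Y-linked genes together had 0 and 2916. The spread between the libraries may be partly technical and may include differences between animals and between sexes. Replicate 1 held 57464573 estimated counts and replicate 2 held 62912053, of which 98.3% in each lay on genes. With 1 group there is no contrast between conditions, and the results are levels, comparisons of genes within each library and differences between the 2 libraries. Levels are given as mean ± SD (n = 2), and an exact two-sided sign test on 2 values cannot go below 0.5. A gene was called different between the libraries when an exact binomial test of its counts passed Benjamini-Hochberg adjustment at 0.05 and the fold was at least 2. That test compares these libraries, not conditions, and has no replicate check, and all intervals and floors cover counting error only.

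The heart libraries held 11214 genes at a TPM of at least 1 in both, of which 10677 were protein-coding and 71 were annotated as lincRNA. Across 11824 genes with a mean TPM of at least 1, log2(TPM + 1) had a Pearson r of 0.957 between the libraries and a Spearman rho of 0.944, across genes, which are not independent replicates. The common biological coefficient of variation between the libraries, from edgeR, was 0.275.

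Transcripts of the mitochondrial genome were the most abundant class. Its 13 protein genes, which encode subunits of the respiratory chain and ATP synthase, held 46.0% of TPM in replicate 1 and 30.3% in replicate 2, or 31.5% and 23.5% of estimated counts. mt-Co1 (ENSMUSG00000064351.1, GRCm38 mitochondrial genome, positions 5328 to 6872), a cytochrome c oxidase subunit, stood at 115908 and 86276 TPM. mt-Atp8 had the highest mean TPM, 108051 ± 62584, from only 61894 and 45983 counts. Its 204-nucleotide transcript had an effective length of 6.51 nucleotides in replicate 1 and 10.97 in replicate 2, so its TPM rests on a very small divisor. With TPM rescaled without mt-Atp8, an alternative chosen after seeing the data, the mitochondrial share was 36.3% and 25.6%.

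The 10 genes of highest mean TPM were mt-Atp8, mt-Co1, Gm29216, mt-Co3, Gm10222, mt-Cytb, Hba-a2, mt-Atp6, Gm28661 and mt-Co2, and the 10 highest genes of each library held 54.9% of TPM in replicate 1 and 43.8% in replicate 2. Gm29216, Gm10222 and Gm28661 are annotated pseudogenes on chromosome 1, between positions 24612407 and 24616197 (GRCm38), that copy mitochondrial sequence. The division of reads between such copies was uncertain. The posterior standard deviation of the count was 429085 for mt-Co3 in replicate 1, and the same for the pseudogene Gm28437, against 2542942 and 468366 counts. The 6 pseudogenes of that stretch held 15.3% and 13.4% of TPM, or 5.23% and 4.12% of counts. Hba-a2, an alpha globin of red blood cells, stood at 3475 TPM in replicate 1 and 43157 TPM in replicate 2.

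**Figure D1:**
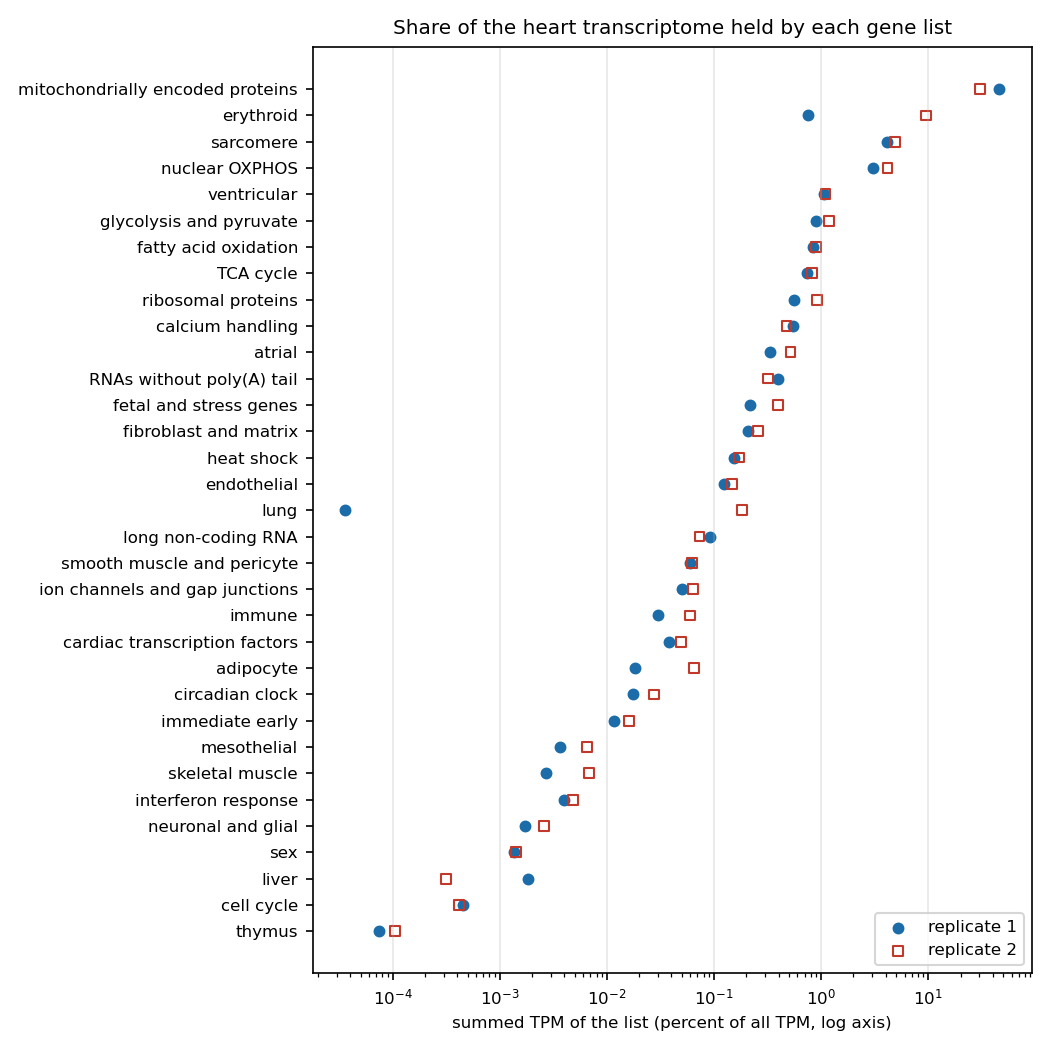
Summed TPM of each fixed gene list as percent of all TPM (log axis), with a filled circle for replicate 1 and an open square for replicate 2. Erythroid genes held 0.759% and 9.49%, while sarcomere genes held 4.08% and 4.90%.

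Contractile proteins were the largest nuclear class of the cardiac lists. The 24 sarcomere genes, which encode thick and thin filaments and the structures that anchor them, were all detected in both libraries and held 4.49 ± 0.576% of TPM. Actc1, the cardiac alpha actin, led at 13787 ± 1044 TPM, followed by Tnni3, the cardiac inhibitory troponin, at 7831 ± 4524 TPM. The ventricular light chains Myl3 and Myl2 stood at 4670 ± 426 and 4001 ± 144 TPM. Between the libraries, 1 sarcomere gene, the skeletal actin Acta1, was called higher in replicate 2 (2.25-fold, not called after GC correction), none was called lower and 23 were not called. The counts were the same when adjusted over the list alone, for this list and for every other list.

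Calcium handling genes, which release and recover the calcium of each beat, were all detected (16 of 16) and held 0.509 ± 0.0504% of TPM. Atp2a2, the calcium pump of the sarcoplasmic reticulum, reached 1903 ± 196 TPM, and its inhibitor Pln reached 1708 ± 396 TPM. S100a1 stood at 627 ± 182 TPM and Casq2, a calcium store protein, at 245 ± 76.6 TPM. No member was called, over all genes or over the list alone. The median log2 ratio of replicate 2 over replicate 1 was -0.38, at percentile 0.13 of random lists matched on expression and at percentile 11.5 of lists matched also on GC content.

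Ion channel and gap junction genes held 0.0569 ± 0.00896% of TPM, and 22 of 23 were detected in both libraries. Kcnip2, an accessory subunit of potassium channels, stood at 105 ± 12.7 TPM, and the ventricular gap junction gene Gja1 at 75.3 ± 7.71 TPM. Among the 20 cardiac transcription factors 18 were detected, together at 0.0434 ± 0.00813% of TPM. Esrra, a regulator of mitochondrial genes, stood at 61.0 ± 13.9 TPM, Gata4 at 56.2 ± 2.24 TPM and Srf at 45.1 ± 9.82 TPM. No tested gene of either list was called between the libraries.

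Genes of energy metabolism were detected throughout. The 34 nuclear genes of oxidative phosphorylation held 3.62 ± 0.777% of TPM, led by the ATP synthase subunits Atp5b (3799 ± 707 TPM) and Atp5a1 (3118 ± 5.29 TPM). Despite that small SD, Atp5a1 was 1.20-fold higher in replicate 1 by TMM-scaled counts, and not called. In that list Cox6a2, the muscle form of a cytochrome c oxidase subunit, and Atp5d were called higher in replicate 2 (2.16-fold and 2.27-fold), and 32 were not called. The 24 genes of fatty acid oxidation held 0.867 ± 0.0481% of TPM, with Fabp3, the heart fatty acid binding protein, at 3320 ± 284 TPM, Lpl at 768 ± 111 TPM and Cpt1b, the muscle enzyme of mitochondrial fatty acid import, at 372 ± 61.6 TPM. Glycolysis and pyruvate genes held 1.04 ± 0.202%, with Gapdh at 3612 ± 1224 TPM. The 17 genes of the TCA cycle held 0.777 ± 0.0561%, with Mdh2 at 1094 ± 247 TPM. No member of the fatty acid, glycolysis or TCA lists was called.

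Markers of both kinds of chamber were present. The 14 atrial genes were all detected and held 0.424 ± 0.130% of TPM, and ventricular genes held 1.08 ± 0.0219%. Nppa, the atrial natriuretic peptide, stood at 1899 ± 667 TPM, Sln at 683 ± 92.7 TPM and Myl7, the atrial light chain, at 636 ± 343 TPM. Myl7 was called higher in replicate 2 (2.01-fold) and 13 atrial genes were not called. The atrial median log2 ratio was 0.30, at percentile 99.3 of random lists, or 97.0 of lists matched also on transcript length, which is inside the central 95%, and the ventricular list, with no gene called, lay at percentile 60.6. Of 12 fetal and stress genes, Acta1, Ankrd1 (2.02-fold) and Gdf15 (10 against 163 counts) were called higher in replicate 2, Xirp2 was called lower (2.13-fold), and 8 were not called. Their median log2 ratio was 0.61, the value of Mybphl, at percentile 99.96. Nppa and Mybphl belong also to the atrial list, and Acta1 and Myh7 to the sarcomere list, so the shifts of these lists are not independent.

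Fibroblast and matrix genes (0.230 ± 0.0354% of TPM), endothelial genes (0.136 ± 0.0170%) and smooth muscle and pericyte genes (0.0609 ± 0.00151%) were all detected in both libraries. Gsn stood at 681 ± 63.1 TPM, Ly6c1 at 272 ± 61.7 TPM and Acta2, the smooth muscle actin, at 338 ± 33.8 TPM. Of these lists Lum, a matrix proteoglycan, was called higher in replicate 1 (2.55-fold) and Cnn1, a smooth muscle protein, higher in replicate 2 (3.12-fold), and the other members were not called. The call of Lum ended after GC correction. Their list medians lay within the central 95% of random lists. Immune genes held 0.0298% and 0.0600% of TPM, and 5 of 17 were called higher in replicate 2, among them the antigen presentation genes Cd74 (2.40-fold) and H2-Ab1 (2.38-fold) and the B cell gene Cd79a (4.12-fold). The immune median was 0.50, at percentile 100. In the same library 7 of 7 lung, 7 of 7 erythroid and 8 of 11 adipocyte genes were also called higher.

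Other lists had few transcripts. Mesothelial genes held 0.00365% and 0.00648% of TPM, and 3 of 8, the epithelial keratins Krt19 (4.67-fold), Krt8 (5.49-fold) and Krt18 (3.34-fold), were called higher in replicate 2, as were the 7 lung genes. The other 5 (Wt1, Upk3b, Upk1b, Msln and Lrrn4) were not called and lay between 1.07-fold and 1.19-fold higher. Neuronal and glial genes held 0.00170% and 0.00257%, with 1 gene called higher and Snap25 lower (2.16-fold) in replicate 2 and 8 not called. Skeletal muscle genes held 0.00271% and 0.00682%, with Myl1 (808 and 2323 counts) and Tnnt3 (1 and 34 counts, a ratio of 28.5 with an exact 95% interval of 4.78 to 1157) called higher in replicate 2, of 6 tested. Of 12 cell cycle genes, Cenpf (413 and 218 counts), Top2a, Cdk1 and Bub1 were called lower in replicate 2 and 8 were not called, although Cenpf had 1.02 and 1.05 TPM, and after GC correction Cdk1 was the 1 member still called. No thymus gene reached a TPM of 1, and Cd8a (16 and 51 counts) was called higher in replicate 2. Interferon response genes held 0.00397% and 0.00483%, with Ifi44 called lower in replicate 2 (2.16-fold) and 11 not called. After GC correction Ifi44 was not called, and Rsad2 (527 and 1019 counts) and Mx1 (24 and 52 counts), chosen after their values were seen, were called higher in replicate 2.

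Genes that respond to handling or to time of day were also detected. Immediate early genes held 0.0138 ± 0.00306% of TPM, with Dusp1 at 60.6 ± 5.79 TPM. None of them was called, and their median log2 ratio of 0.32 lay at percentile 98.1, or 87.4 against lists matched also on GC content and 97.4 against lists matched also on transcript length. Heat shock genes held 0.163 ± 0.0122%, led by Hspa8 at 1265 ± 1.35 TPM, and Hspa1a and Hspa1b, near-identical copies whose reads cannot be separated with certainty, were called higher in replicate 2. By TMM-scaled counts Hspa8 was 1.47-fold higher in replicate 1 (70319 and 57139 counts, not called), so the small SD of its TPM does not mean equal levels. Of 15 clock genes, Per1 (2.77-fold), Dbp (2.56-fold) and Ciart (2.24-fold) were called higher in replicate 2. The clock median of 0.20 lay at percentile 94.2, or 98.1 of lists matched also on transcript length. That median hides moves in opposite directions, since 10 of the 15 genes had a log2 ratio above 0. Cry1 (1.75-fold), Arntl (1.74-fold) and Clock (1.68-fold), chosen after their values were seen, were higher in replicate 1 before GC correction and not called.

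Ribosomal protein genes held 0.559% and 0.914% of TPM. Rplp1 (2.30-fold) and Rps27 (40 and 186 counts) were called higher in replicate 2, and the list median of 0.36 lay at percentile 99.96. Long non-coding RNAs held 0.0826 ± 0.0133%, and the nuclear RNA Malat1 (2.07-fold) and the imprinted H19 (2.32-fold) were called higher in replicate 1. Mhrt, an antisense RNA of the myosin locus, stood at 78.4 ± 6.71 TPM. RNAs that carry no poly(A) tail held 0.357 ± 0.0551%, mostly from Rn7sk at 3706 and 2859 TPM, and none of the 3 tested was called.

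Related genes were compared within each library. Of 30 pairs, the gene named first, an order fixed beforehand, was higher in both libraries in 29. Myh6, the fast myosin of the adult mouse heart, stood at 1776 and 1685 TPM against 4.94 and 8.61 TPM for Myh7, the slow form, a mean log2 ratio of 8.05 ± 0.62. The log2 ratio was 13.15 ± 1.14 for Tnni3 over Tnni1 and 4.59 ± 1.06 for Actc1 over Acta1. Tnnc2, the skeletal troponin C, had 1 count in each library against 66539 and 88193 for Tnnc1. Ryr1 had 7 and 4 counts against 66686 and 47556 for Ryr2, the cardiac calcium release channel.

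In the metabolic pairs the first gene also led by TPM, except Ppara over Pparg in replicate 2. The log2 ratio was 4.69 ± 0.09 for Cpt1b over Cpt1a, 4.86 ± 0.24 for the insulin-responsive glucose transporter Slc2a4 over Slc2a1, and 5.44 ± 0.01 for the muscle creatine kinase Ckm over Ckb. The margins were narrower for Ldhb over Ldha (1.31 ± 0.18), Hk2 over Hk1 (0.81 ± 0.38) and, outside metabolism, Pln over Sln (1.31 ± 0.53). Ppara and Pparg, nuclear receptors of fat metabolism, stood at 8.90 against 4.15 TPM in replicate 1 and at 6.84 against 7.20 TPM in replicate 2. Their mean log2 ratio of 0.51 ± 0.83 was smaller than its spread. By estimated counts the first gene also led in both libraries in 29 pairs, but there Ppara led Pparg in both (1441 against 414 and 1210 against 755) and Cox7a1 had fewer than Cox7a2 in replicate 1 (9961 against 10920).

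**Figure D2:**
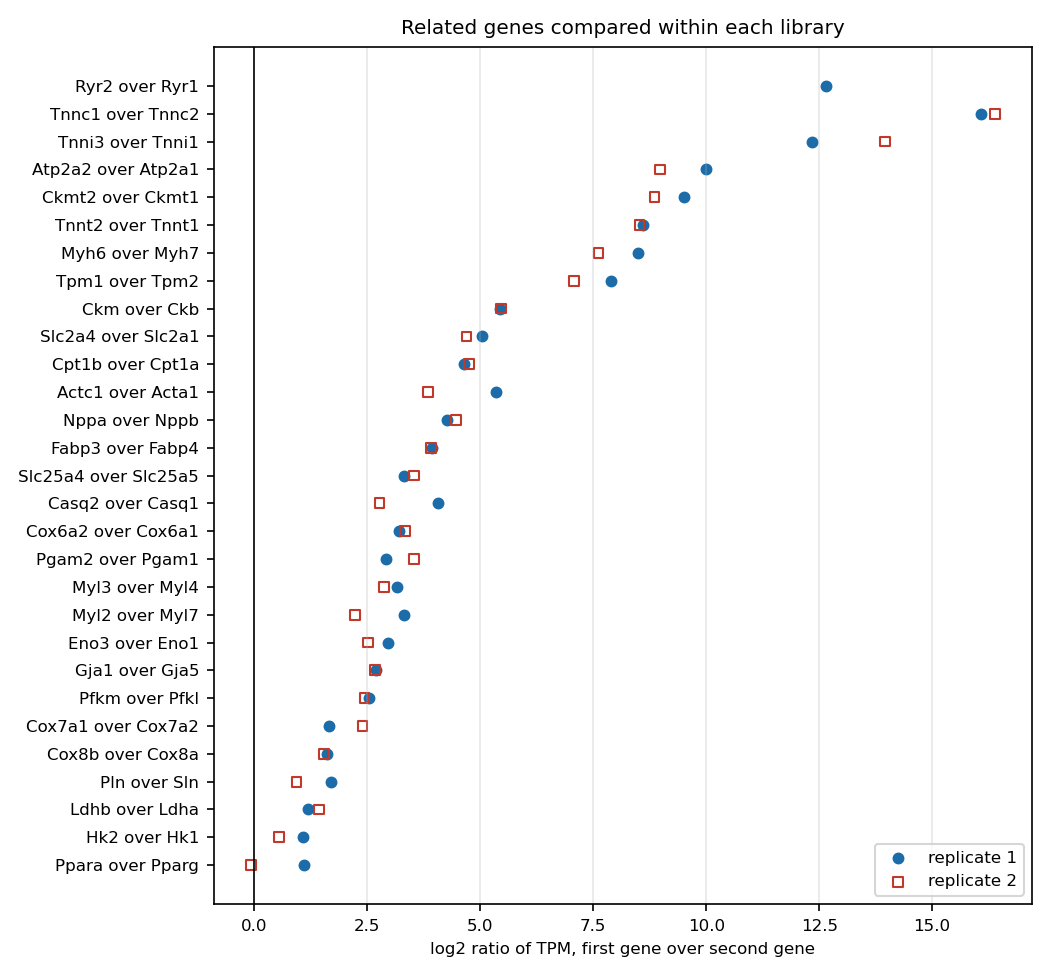
log2 ratio of TPM of the first gene over the second gene for each pair reported here, with a filled circle for replicate 1 and an open square for replicate 2 (a gene listed at 0 leaves its point out). The plotted points lie above 0 except Ppara over Pparg in replicate 2 (-0.07).

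At the transcript level, the same annotated transcript led in both libraries for 21 of 22 genes chosen for their splicing in heart. Fhod3 and Trdn had 1 annotated transcript each and were left out of that count. The leading transcript held 97.2 ± 0.687% of Tpm1, 98.9 ± 0.632% of Ryr2 and 92.8 ± 2.21% of Pkm. Ttn, the giant spring protein of the sarcomere, was led by a transcript of 81843 nucleotides at 61.8 ± 0.315%. For Nebl the leading share was 42.9% and 65.8%, for a transcript of only 335 nucleotides that did not lead in both libraries by estimated counts. Across 3530 genes with a mean TPM of at least 10 and 2 or more expressed transcripts, 86.5% kept the leading transcript (Wilson 95% interval 85.4% to 87.6%).

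Transcripts of the sex chromosomes separated the libraries, although the labels describe both as drawn from males and females together. Xist (ENSMUSG00000086503.3, GRCm38 chromosome X, positions 103460366 to 103483254), the RNA that silences an X chromosome in females, had 13725 counts in replicate 1 and 13 in replicate 2, a 1261-fold difference (exact 95% interval 737 to 2369). All 4 Y-linked genes had 0 counts in replicate 1. Replicate 2 held 922 counts for Ddx3y (ENSMUSG00000069045.7, chromosome Y, positions 1260771 to 1286629), 777 for Kdm5d, 759 for Eif2s3y and 458 for Uty. Against a floor of 3 counts in replicate 1 these were at least 257-fold, 217-fold, 212-fold and 128-fold higher. Ddx3x, Eif2s3x and Kdm6a, X-linked genes known to escape silencing and chosen after their values were seen, were called higher in replicate 1 (2.36-fold, 2.36-fold and 2.44-fold).

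Between the libraries, 1901 of 16145 tested genes were called, 1325 higher in replicate 2 and 576 lower. The majority depended on the fold limit, since without it 5313 were higher and 5628 lower, and with scaling by total counts 1602 were higher and 415 lower. Among genes with a mean CPM of at least 10, the 10 largest folds toward replicate 2 were those of Bpifa1, Scgb1a1, Bpifb1, Scgb3a2, Muc5b, Scgb3a1, Cyp2a5, Cyp2f2, Wfdc2 and Eno1b, several of them known products of airway epithelium. Scgb1a1 (ENSMUSG00000024653.2, GRCm38 chromosome 19, positions 9083636 to 9087958), the club cell secretoglobin, had 3 counts in replicate 1 and 28741 in replicate 2, a ratio of 8022 (exact 95% interval 2745 to 38903). Bpifa1 had 2 and 20852 counts, a ratio of 8730.5 (2417 to 72095). Scgb3a2 had 0 and 5354 counts, at least 1494-fold higher. The sequence of Eno1b is close to that of Eno1, so its reads may be shared.

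Toward replicate 1 the 10 largest folds were those of Xist, Gm10259, Kcnj14, Alb, Gm9625, Cyp26b1, Gm8730, Tpt1-ps3, Abhd1 and mt-Nd6. Alb, the main plasma protein made by liver, had 1064 and 38 counts (33.4-fold), and Cyp26b1, a retinoic acid hydroxylase, had 2651 and 261 counts (12.1-fold). Gm10259, Gm9625, Gm8730 and Tpt1-ps3 are annotated as processed pseudogenes, and their counts are uncertain because reads can be shared with their parent genes. With edgeR's exact test at the common dispersion of the libraries, 411 of the 1901 genes were called, 338 higher and 73 lower, without Abhd1 and mt-Nd6. That dispersion was estimated from the difference between these same libraries, so it is not a separate measure of replicate error. In data simulated with it, 8.94% of unchanged genes were called by the binomial test and fold limit, against 11.8% of tested genes here.

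**Figure D3:**
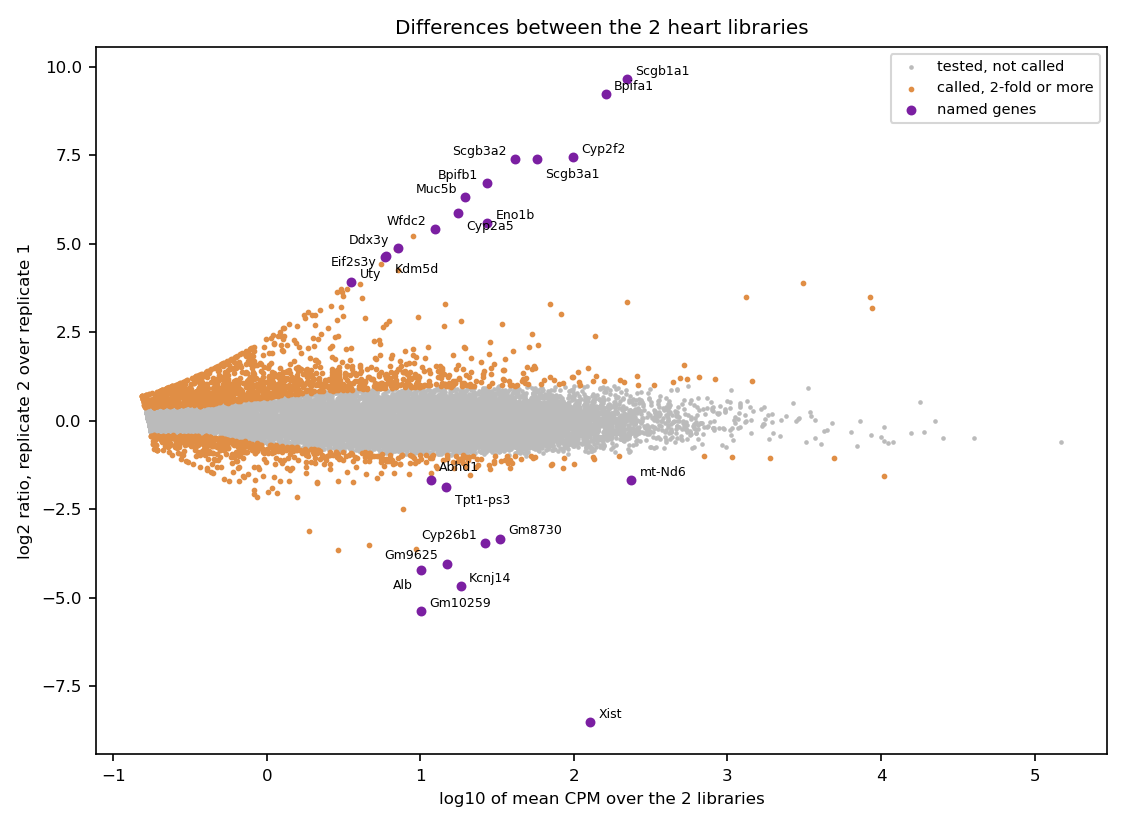
log2 ratio of replicate 2 over replicate 1 (TMM-scaled CPM + 0.5) against log10 of mean CPM for each tested gene, with called genes in orange and named genes in purple. The added 0.5 CPM pulls low genes toward 0, so some called genes plot under a 2-fold difference; Scgb1a1 (9.65) and Xist (-8.50) mark the ends.

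Of 28 fixed lists with at least 4 measured members, 11 had a median outside the central 95% of 10000 random lists, 9 above and 2 below. All 7 lung genes were called higher in replicate 2, among them the surfactant genes Sftpc (2 and 718 counts, a ratio of 301 with an exact 95% interval of 82.9 to 2487) and Sftpb (0 and 396 counts). The median log2 ratio of the 5 lung genes measured was 4.43, or 7.65 with the 3-count floor and 1.68 with a pseudocount of 5 CPM. All 7 erythroid genes with data were called higher, with a median of 3.35. Hbb-bs was 9.16-fold higher and Alas2, the erythroid enzyme of haem synthesis, 10.3-fold, while Hba-a2 (11.2-fold) and Hba-a1 (14.8-fold) are near-identical copies and uncertain one by one. Adipocyte genes had 8 of 11 called higher and a median of 1.39, with Cfd at 8.23-fold, Adipoq at 2.68-fold and Ucp1, the uncoupling protein of brown fat, at 2.19-fold. The sex list, with 4 of 5 genes higher, had a median of 4.61, or 7.73 with the floor, 2.51 with TPM ratios and 1.74 with the larger pseudocount. Xist, its other member, went the opposite way. The place of this list among the 9 above therefore follows from how many Y-linked genes it holds and is not a shift of the whole list.

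The 7 liver genes were all called higher in replicate 1, among them Alb, Ttr (97 and 31 counts) and Apoa2 (100 and 38 counts). The 13 mitochondrially encoded genes had a median of -0.56, at percentile 0 of random lists, with mt-Nd6 called (3.21-fold higher in replicate 1) and 12 not called. They lay at percentile 12.5 of lists matched also on GC content, an alternative chosen after seeing the data under which 8 of the 11 lists stayed outside.

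**Figure D4:**
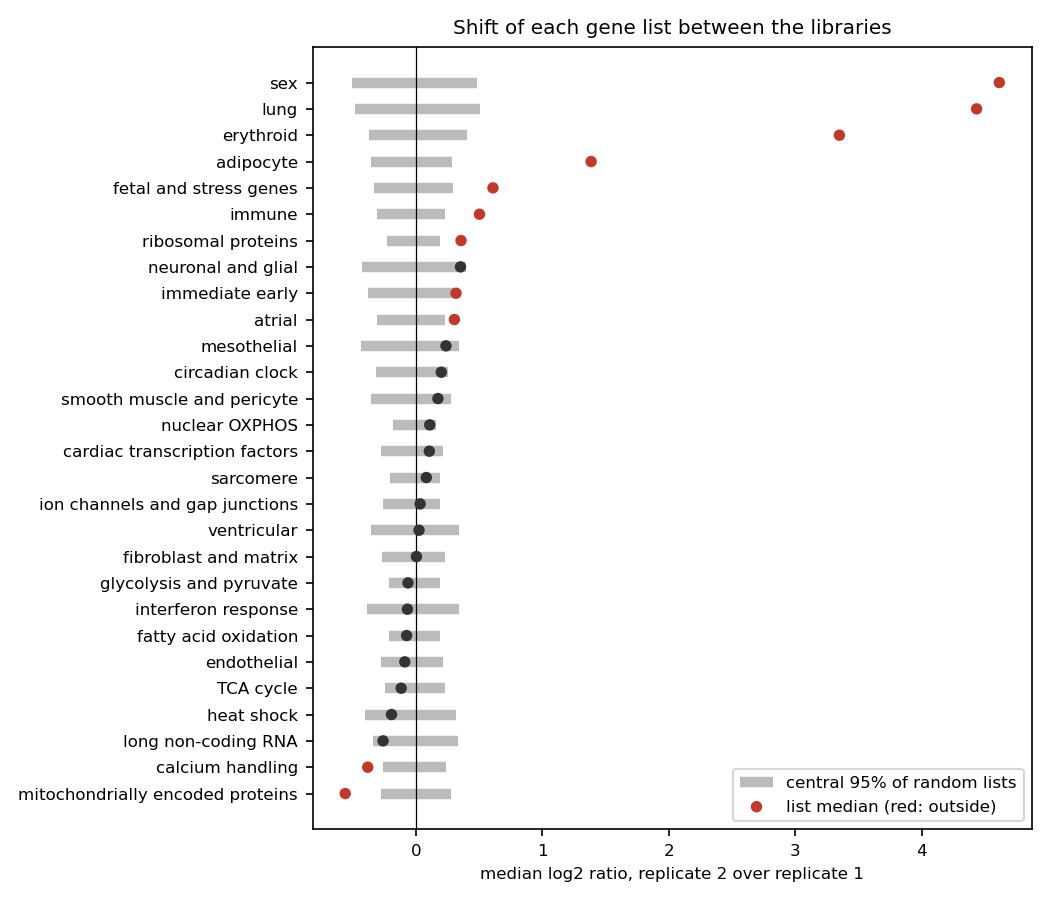
Median log2 ratio of replicate 2 over replicate 1 for each list with at least 4 measured members (points, red when outside) and the central 95% of 10000 random lists matched on expression (grey bars). Sex (4.61), lung (4.43), erythroid (3.35) and adipocyte (1.39) genes lie furthest to the right, in an order that changes with the pseudocount and unit (erythroid 3.21, sex 1.74, lung 1.68 and adipocyte 1.08 with 5 CPM added), and mitochondrially encoded proteins (-0.56) and calcium handling (-0.38) lie to the left of their bars. The sex median is set by the Y-linked genes of that list, while Xist went the opposite way.

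The ratio between the libraries also followed base composition. Across 12519 protein-coding genes, the log2 ratio had a Spearman rho of 0.68 with GC content, across genes, which are not independent. Median log2 ratios ran from -0.53 in the lowest of 10 classes of GC content to 0.48 in the highest. After a GC correction, chosen after seeing the data, 1459 genes were called, 1149 higher in replicate 2 and 310 lower, of which 1274 were called in the same direction without it. Of 71 list genes called without the correction, 55 were called in the same direction after it. The call ended for the other 16, which were Acta1, Atp5d, Xirp2, Myl7, Lum, H2-Ab1, Lipe, Snap25, Hspa1a, Dbp, Top2a, Bub1, Cenpf, Ifi44, Malat1 and Rplp1. The 4 list genes called only after it were Nr2f2, H2-Aa, Rsad2 and Mx1, chosen after their values were seen. A call that ended or began marks a passage of the test's limits and need not mean a difference removed or made. The log2 ratio moved from 1.24 to 0.92 for H2-Ab1, from 1.17 to 0.87 for Acta1, from 1.01 to 0.85 for Myl7 and from 0.93 to 1.00 for H2-Aa. Other genes changed more: Snap25, 2.16-fold lower before the correction, was less than 1.5 times lower after it.

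Added control RNAs gave a measure outside the tissue. Of 96 spike-in sequences, 75 had a count in replicate 1 and 74 in replicate 2. They took 1.65% of counts in replicate 1 (Wilson 95% interval 1.647% to 1.654%) and 1.72% in replicate 2 (1.721% to 1.727%). Among the 27 with at least 1000 counts, the log2 ratio between the libraries had an SD of 0.21, against a median counting error of 0.02.

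Lists of splice junctions and transcribed contigs on the mm9 build, given without a library, were described by themselves. The junction list held 362268 junctions and 35016870 reads, with a median intron of 1977 nucleotides, and 38.0% of junctions had 1 read. The most used junction, of 134 nucleotides on chromosome 11 at positions 32184129 to 32184262 (mm9), had 644228 reads. The contig list held 628453 contigs with a summed length of 208404252 nucleotides and a median of 193.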

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

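The test of whether each library pools both sexes was chosen only after the result was seen, and the test of the R1 and R2 numbering was prompted by chromosome Y and globin junctions, so the sex, erythroid and lung genes and chromosomes X and Y were left out of it.

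Junction reads on chromosome Y appeared in a list that the comparisons of the libraries do not use, above what a count of 0 allows. The mm9 junction list held 1539 such reads under R1 and 25 under R2. Among junctions matched to genes by intron length, Ddx3y had 280 under R1 and 0 under R2, while Xist had 0 under R1 and all of its reads under R2.

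Sex-linked transcripts were split between the 2 libraries. The tables argue against both libraries being pools of males and females. The 4 Y-linked genes of the sex list had 0 counts in replicate 1. Counting error allows them at most 0.123% of their replicate 2 level there. Xist in replicate 2 was at 0.0793% of its replicate 1 level. The limit of 0.123% does not cover other chromosome Y sequence. The junction list held 25 chromosome Y reads under R2, against 1539 under R1. The tables also argue against reads lost by depth or GC content. Of 499 autosomal genes of the same range of counts and GC content, 0% had 3 or fewer counts in replicate 1. The opposite order in the junction list is consistent with R1 and R2 being numbered the other way round, since the log2 ratio of R1 over R2 followed that of replicate 2 over replicate 1 across 7247 genes matched by intron length (Spearman rho 0.670). A sample of females in replicate 1 and of males in replicate 2 stays open as a hypothesis that these values allow. It was found and tested on the same data, and no label gives the sex of each sample. If it holds, each comparison of the libraries and each SD also includes any difference between the sexes, which the design cannot separate.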

How the results depend on the processing

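The GC-corrected values, the random lists matched on GC content, the calls without markers of other cells and tissues, the correlation without mitochondrial genes and the TPM without mt-Atp8 were chosen only after the result was seen. No list with a median outside the random range changed sign with TPM ratios, total counts or a pseudocount of 5, and 0 called genes were called in the opposite direction after GC correction. Among lists inside the range, 7 medians changed sign with TPM ratios, such as heat shock genes (-0.19 to 0.20) and long non-coding RNAs (-0.26 to 0.06), and 5 with total counts. The log2 ratio of 93 uncalled genes, of 479 list and named genes tested, changed sign after GC correction, as did that of 40 of 1877 called genes on the scale with 0.5 CPM added. With each library left out in turn, genes detected ranged from 11565 to 11935, the share of TPM in the lists from 55.3% to 59.1%, pairs with the first gene higher from 29 to 30 (29 by counts and 30 with posterior mean TPM), the mitochondrial share from 30.3% to 46.0%, the top 10 share from 43.8% to 54.9% and the spike-in share from 1.65% to 1.72%. The correlation, coefficient of variation, calls, list shifts and shared leading transcripts need both libraries, so no such value exists for them. A TPM of at least 5 left 6505 genes. The correlation was 0.938 with a pseudocount of 0.1, 0.985 without a filter and 0.930 at a mean TPM of at least 10. The coefficient of variation was 0.359 without a filter, 0.3004 at 100 counts and 0.223 after GC correction. Calls numbered 928 at 100 counts, 10941 without a fold limit (5313 higher and 5628 lower), 626 at 4-fold and 411 with edgeR's exact test; total counts shifted every log2 ratio by 0.13 and called 2017 (1602 higher and 415 lower). The lists held 47.1% by counts, 30.2% without mitochondrial genes and 52.0% without mt-Atp8. The leading transcript was kept in 83.9% at a mean TPM of at least 1, 90.6% at 100 and 92.1% by counts. The top 10 genes held 32.5% by counts and 35.5% without mitochondrial genes, and spike-ins held 1.76% of TPM. A significance field of at most 0.1 left 131851 junctions and 279122 contigs. Matching on GC content moved calcium handling, mitochondrial and immediate early genes inside and nuclear oxidative phosphorylation outside (percentile 99.8). Matching on length moved atrial and immediate early genes inside and the clock outside (98.1). Stricter filters test fewer genes; otherwise the cause was not tested.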

Other observations

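The tests of the GC content trend and of other tissue in the sample of replicate 2, and the GC-corrected values, were chosen only after the result was seen.

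Mitochondrial ribosomal RNAs, chosen after their values were seen, were higher in replicate 1, with mt-Rnr1 at 50884 and 30281 counts (2.01-fold) and mt-Rnr2 at 360986 and 206396 counts (2.09-fold), and their log2 ratios were -0.43 and -0.49 after GC correction. Gm42418, also chosen after its values were seen, stood at 7870 and 12773 TPM. After GC correction the log2 ratios of Kdm6a, Eif2s3x and Ddx3x were -1.03, -0.85 and -0.72.

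Lung, erythroid and adipocyte transcripts were higher in replicate 2. The tables argue against the GC content trend as the whole cause. The median log2 ratio of 25 members was 1.97 before and 2.47 after GC correction, with a lower quartile of 1.37. They also argue against scaling, since with spike-in scaling the median was 2.03 and the lower quartile 1.51. Both outcomes followed from the small size of the corrections. The GC classes had medians of only -0.53 to 0.48, and spike-in scaling moved every log2 ratio by 0.06. Lung or airway tissue in the sample of replicate 2 is a candidate explanation for the lung transcripts. There the club cell gene Scgb1a1 stood at 1567 TPM, against 18 TPM for the surfactant gene Sftpc and 4.78 TPM for Sftpb. Which part of the lung or airway such transcripts came from was not tested. After GC correction 14 of 14 detected further markers of lung were at least 1.5 times higher (100%, exact 95% interval 76.8% to 100%). Among 14390 genes in the same range of counts 15.0% were. That share cannot decide the question. Markers such as Cldn18, Nkx2-1, Epcam and Elf3 had 0 counts in replicate 1 and were detected through replicate 2 alone. For fat the share was 6 of 10 (60%, 26.2% to 87.8%, against 10.6%), which only just reached the bound set, while Elovl3 was called lower (52 and 14 counts) and Slc36a2, Dgat2 and Aqp7 stayed below 1.5 times, and red blood cells cannot be told apart from other sources, since 3 of 5 further markers (Epb42, Tspo2 and Trim10; 60%, 14.7% to 94.7%) are too few to set apart from the 30.8% of other genes. These hypotheses were found and tested on the same data, in replicate 1 a TPM of at least 1 was reached by 0 of 7 lung, 5 of 7 erythroid and 10 of 11 adipocyte genes of the fixed lists and by 1 of 14, 1 of 5 and 8 of 10 further markers, and liver genes went the other way (median -1.10 after correction).

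The log2 ratio of the libraries rose with GC content. Transcripts of other tissues do not account for it, since rho was 0.683 over 11905 genes without those lists and without genes of 2-fold difference, against 0.676 over 12519. Short transcripts do not account for it either, since rho with GC content given transcript length was 0.656, while rho with length was -0.25. A composition bias of library preparation or sequencing stays open and cannot be told apart from other sources of the trend: rho was positive in 100% of 21 lists with 10 or more measured members, from 0.26 to 0.76, which any trend across all genes would give. Apart from transcripts of other tissues, no biological explanation of the trend was tested, because the design gives 1 group.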
